A study of Mus musculus with 16 samples.

How the data were processed

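The series measured RNA in whole mouse liver by sequencing of 16 libraries. Mice drank thioacetamide, a compound that injures the liver and is used to make fibrosis, at 300 mg/L for 8 weeks. They then recovered for 1, 2 or 4 weeks on water with or without choline chloride at 3.5 g/L. The sample titles give 8 groups of 2 libraries: an untreated control, the end of thioacetamide (called TAA), and recovery without and with choline at each of the 3 times. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

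Per the labels, total RNA was extracted with TRIzol, ribosomal RNA was depleted, and libraries were made with a directional kit. The deposited table of expected counts holds estimated reads per gene, not normalised and not all whole: 8.7% of the values had a fractional part. A table of TPM, deposited by the authors, gives each library the same total and was used here only for the share taken by 7SL RNA genes. STAR 2.7.10b, RSEM 1.3.3, DESeq2 1.36.0 and the genome build GRCm38 are named in the submitters' processing notes without their roles. The annotation release, the filters and the strand setting of the counting are not given in the sources used here. Genes that overlap or lie antisense to another are therefore uncertain, and so are near-identical copies of the Mup, Cyp2a, Cyp2b, Cyp3a, Cyp4a and Hba families, whose shared reads the estimation divides between copies. In the deposited tables, 2 columns of values matched no sample and were not used. Gene coordinates are those of the deposited tables.

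Totals per library ranged from 23.1 to 33.6 Mcounts (mega-counts). The table held 55401 genes, of which 29692 had a count in any library, and every counted gene had a name. In each library 18872 to 22937 genes had 1 count or more. No pair of replicates held the same counts: the chi-square per degree of freedom between the libraries of a group ran from 14.7 to 244.2, far above sampling noise, so each library counted as 1 sample.

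Expected counts were rounded to whole numbers. The filterByExpr filter of edgeR 4.0.16 kept 17292 genes, and library sizes were scaled by TMM. One quasi-likelihood fit with robust spread (edgeR in R 4.3.3) took the mean of each of the 8 groups from all 16 libraries, which leaves 8 residual degrees of freedom. All p-values of genes are from its two-sided tests, Benjamini-Hochberg adjusted over the 17292 genes within a comparison. A gene is called at an adjusted p under 0.05. Log2 fold changes are given with their standard errors and levels as CPM, counts relative to the scaled library size, mean ± SD over n = 2. The comparisons were TAA against control, each recovery time without choline against TAA and against control, choline against no choline at each time and as the mean over the 3 times, and the interaction of choline with time.

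Gene lists for the pathways and cell types of the injured liver, 35 in number, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, adjusted over lists within a comparison. Of the 598 genes in them, 597 were in the table, and 33 lists had the 5 tested genes required. The same test with a correlation estimated within each list is given beside each list described as changed, and for week differences as a group. Counts of called members are given over all genes tested and adjusted over the list alone. With libraries regrouped at random within a week, lists passed the preset test as often as in the real grouping, so a call at the preset correlation is not evidence by itself.

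Unless stated otherwise, the lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Tests and lists added later are named as such where they appear. For each comparison the rule took the largest log2 changes in each direction among called genes that had a mean of at least 5 CPM in the higher group and whose groups did not overlap, leaving out predicted and unnamed loci. It took 10 in each direction for TAA against control and for choline and 5 for the others. For the mean over the 3 times, a change of the same sign at each time replaced the condition on overlap. It added up to 4 members with the smallest p from each called list and a fixed set of collagen, sterol, bile acid, choline and lipid genes. Where fewer than 3 genes passed, it took the 5 genes with the smallest p, named as not passing. Words such as largest, most raised or most lowered rank only genes that passed this rule. The text takes genes in that order without using all of them, and values of 2 genes that it took are not reported here, and any gene outside the rule is said to have been chosen after its values were seen.

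Alternatives were size factors of DESeq2, the test of DESeq2 1.42.0, no filter, fits of the compared groups alone, the replicate number as a block, an additive model of time and choline, and each library left out in turn. The additive model was fitted to the 12 recovery libraries only. A group left with 1 library was assumed to vary like the others. After seeing the data, fits without both libraries low in Malat1 were added, which leave 1 library each in control and TAA. The replicate numbers in the titles were not taken as a pairing, although the replicate differences of control and TAA correlated at 0.59.

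Counts were simulated from the real means, spreads and library sizes, with changed genes drawn from those with a mean of at least 5 CPM. TAA against control called 38% of genes changed 2-fold and 94% of those changed 4-fold. Choline at 4 weeks called 44% and 95%, and the mean over the 3 times 94% and 99%. False calls numbered 10, 7 and 7 of the 17292 genes, and 0 of 20 random lists were called in each of the 3. The simulated genes varied independently and no simulated library stood apart, so the real data may do worse. For genes with 3 counts or fewer in a group, levels or counts are given in place of a fold. Tables and figures were made with R and with matplotlib 3.10.9 in Python 3.11.15.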

Results

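The 16 libraries came from whole mouse liver and fell into 8 groups of 2: control, TAA (8 weeks of thioacetamide), and recovery for 1, 2 or 4 weeks without or with choline. Totals ranged from 23.1 to 33.6 Mcounts (mega-counts) per library, and 17292 genes passed the filter on low counts. Genes of 7SL RNA, the RNA of the signal recognition particle, took 5.82% to 15.88% of the counts of a library and 37.8% to 60.5% of its TPM. The first principal component held 38.6% of the variance and the second component 20.3%. On the first, control replicate 1 lay at -165 and TAA replicate 1 at -66.6, and the other 14 libraries between -10.7 and 40.1.

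Malat1 and Neat1, long non-coding RNAs kept in the nucleus, were low in 2 libraries; both genes were chosen after their values were seen. Malat1 (GRCm38, chromosome 19, 5795690 to 5802672) stood at 146 CPM in control replicate 1 and 1020 CPM in TAA replicate 1, against 5230 to 6800 CPM in the other 14 libraries. Neat1 stood at 36.8 and 107 CPM in the same libraries, and the experimentally unverified (TEC) and sense-intronic transcript classes took 0.016% and 0.0526% of counts against 0.1835% to 0.2954% elsewhere. In control replicate 2 the immediate early genes Fos and Egr1, which respond to stimuli within minutes, stood at 64.8 and 211 CPM against 0.366 and 1.23 CPM in control replicate 1. The replicates of control and of TAA differed more than those of other groups, with chi-square per degree of freedom of 244.2 and 118.2 against 14.7 to 44.7. Most counts of called genes below are also given without both libraries low in Malat1, a choice made after seeing the data. Those fits leave only replicate 2 of control and of TAA. Their counts against control or TAA rest on that single library and take their spread from the recovery groups.

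**Figure D1:**
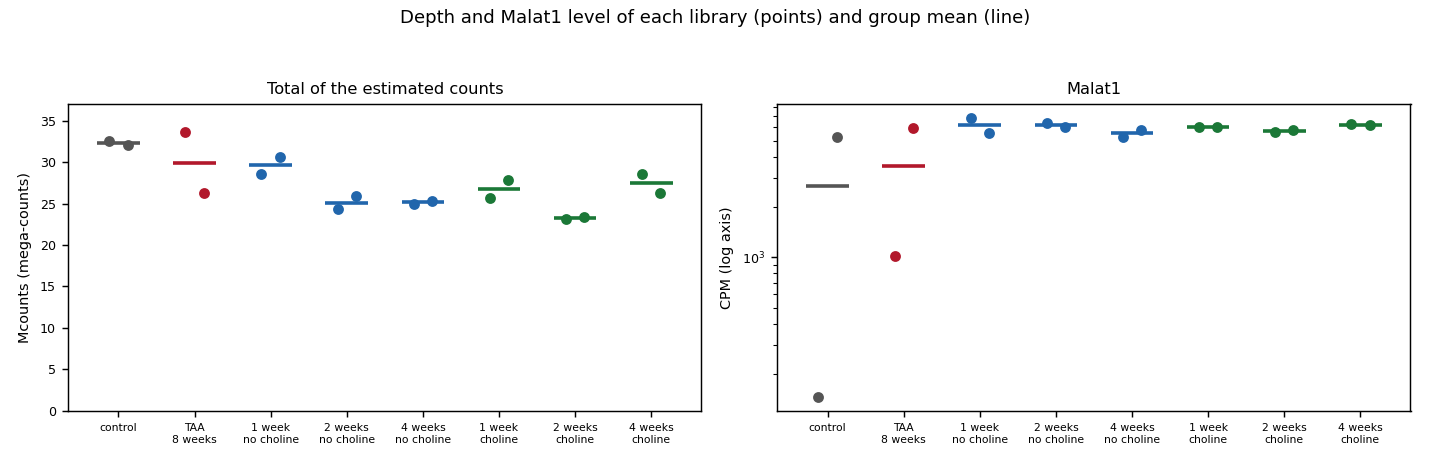
Total counts (mega-counts, Mcounts) and Malat1 in CPM on a log axis, 1 point per library, for the 8 groups of 2. Malat1 lies at 146 CPM in control replicate 1 and 1020 CPM in TAA replicate 1, and between 5230 and 6800 CPM in the other 14 libraries.

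The first comparison asked what 8 weeks of thioacetamide did to the liver. Genes of extracellular matrix and myofibroblasts, the scar-forming cells, rose: 17 of 27 tested members were called higher and 0 lower (25 and 0 adjusted over the list alone). The matrix median was 1.59 (adjusted p = 3.23e-09, and adjusted p = 0.22 with an estimated correlation). Col1a1, the main chain of fibrillar collagen (chromosome 11, 94936224 to 94953042), was 18.6-fold higher (log2 4.22 ± 0.52 SE, n = 2 per group, edgeR adjusted p = 0.000421), and Col5a2, another fibrillar collagen, 6.28-fold higher (2.65 ± 0.24, edgeR adjusted p = 0.000124). Markers of cholangiocytes, the bile duct cells, rose in 11 of 15 members (11 adjusted over the list alone), among them the tight junction gene Cldn4 (5.06 ± 0.71) and the epithelial transcription factor Ehf (4.35 ± 0.72). The cholangiocyte median was 3.15 (adjusted p = 2.04e-06, and adjusted p = 0.259 with an estimated correlation), and 1.9 without TAA replicate 1. Markers of macrophages derived from monocytes rose in 7 of 13 (10 adjusted over the list alone), with the lipid receptor Trem2 at 3.23 ± 0.55 and the chemokine receptor Cx3cr1 at 3.02 ± 0.61. The macrophage median was 1.52 (adjusted p = 8.46e-06, and adjusted p = 0.204 with an estimated correlation). The myofibroblast actin Acta2 (1.59 ± 0.54, edgeR adjusted p = 0.055) and the protease inhibitor Timp1 (2.32 ± 0.78, edgeR adjusted p = 0.0535) did not pass the threshold.

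Cell cycle genes rose with thioacetamide in 19 of 30 members (21 adjusted over the list alone). The cell cycle median was 2.35 (adjusted p = 3.23e-09, and adjusted p = 0.242 with an estimated correlation). The mitotic cyclin Ccnb1 (chromosome 13, 100778650 to 100786570) was 18.8-fold higher (4.23 ± 0.57) and the G1 cyclin Ccnd1 5.65-fold higher (2.5 ± 0.28). Targets of p53, the DNA damage response factor, rose in 11 of 14 (11 adjusted over the list alone), led by the death receptor Eda2r (chromosome X, 97333840 to 97377216; 20.7-fold, 4.37 ± 0.29) and the RNA-binding gene Zmat3 (2.55 ± 0.23). The p53 target median was 1.73 (adjusted p = 3.23e-09, and adjusted p = 0.0493 with an estimated correlation). Targets of NRF2, the regulator of the response to oxidants, rose in 15 of 19 (16 adjusted over the list alone), including Srxn1, which repairs oxidised peroxiredoxins (2.19 ± 0.22), and Pgd of the pentose phosphate pathway (1.75 ± 0.18). The NRF2 target median was 1.31 (adjusted p = 2.12e-09, and adjusted p = 0.204 with an estimated correlation). Genes of the fetal or transformed liver rose in 7 of 10 (8 adjusted over the list alone), with alpha-fetoprotein, Afp, 38-fold higher (5.25 ± 0.47) and the Golgi gene Golm1 6.42-fold higher (2.68 ± 0.23). The oncofetal median was 3.76 (adjusted p = 6.46e-07, and adjusted p = 0.0493 with an estimated correlation). Cholesterol synthesis genes went both ways, with 8 of 20 called higher and 2 lower (11 and 2 adjusted over the list alone), and the sterol enzyme Sqle (3.07 ± 0.47) was higher. The cholesterol synthesis median was 0.63 (adjusted p = 0.0132, and adjusted p = 0.511 with an estimated correlation). The call of this list ended without TAA replicate 1 (median 0.33, adjusted p = 0.422) and without control replicate 2 (0.34).

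Genes of the working hepatocyte fell with thioacetamide. Of 25 bile acid genes 17 were lower and 2 higher (18 and 3 adjusted over the list alone), including the bile acid importer Slc10a1 (4.56-fold lower, -2.19 ± 0.2), the sterol hydroxylase Cyp27a1 (2.56-fold lower) and Cyp8b1, the enzyme that makes cholic acid (-2.86 ± 0.51). The bile acid median was -1.35 (adjusted p = 8.18e-09, and adjusted p = 0.126 with an estimated correlation). Choline and one-carbon genes were lower in 19 of 29 and higher in 0 (21 and 1 adjusted over the list alone), with Ahcy, which clears S-adenosylhomocysteine, at -2.18 ± 0.32 and the sarcosine enzyme Sardh at -1.24 ± 0.22. The one-carbon median was -0.76 (adjusted p = 9.54e-08, and adjusted p = 0.143 with an estimated correlation). Pericentral hepatocyte genes were lower in 10 of 15 and higher in 2 (10 and 2 adjusted over the list alone), led by glutamine synthetase, Glul (13.2-fold lower, -3.72 ± 0.2, edgeR adjusted p = 6e-06), and the cytochrome Cyp2c37 (-3.77 ± 0.32). The pericentral median was -1.69 (adjusted p = 2.21e-06, and adjusted p = 0.204 with an estimated correlation). Periportal genes were lower in 8 of 14 and higher in 1 (9 and 1 adjusted over the list alone), including the urea cycle gene Otc (-2 ± 0.32) and the tyrosine enzyme Hpd (-2.24 ± 0.36). The periportal median was -0.84 (adjusted p = 7.5e-05, and adjusted p = 0.22 with an estimated correlation). Male-biased liver genes were lower in 10 of 11 (10 adjusted over the list alone), with Cyp4a12b at -4.22 ± 0.49. The male-biased median was -3.6 (adjusted p = 7.2e-09, and adjusted p = 0.204 with an estimated correlation). The sex of the mice is not given in the sources used here.

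Among the largest changes with thioacetamide, the steroid hydroxylase Cyp2a4 was 1910-fold higher (log2 10.9 ± 1.02), and Cyp2b9 was 183-fold higher (7.52 ± 1.7). Slc7a11, the cystine importer, rose from 0.04 ± 0.00813 to 24.7 ± 2.76 CPM, and the matrix protease Mmp7 from 0.0628 ± 0.0405 to 16.3 ± 12 CPM (SD, n = 2). The basement membrane gene Tinag rose from 0.04 ± 0.00813 to 10.6 ± 3.11 CPM, Sybu from 0.0457 ± 0.0647 to 5.32 ± 1.35 CPM and Gipc2 from 0.0628 ± 0.0405 to 5.93 ± 0.34 CPM. Gpnmb, a macrophage glycoprotein, was 101-fold higher (6.66 ± 0.74), the signalling gene Bmp8b 62.9-fold (5.97 ± 0.6) and the carbonyl reductase Cbr3 62.8-fold (5.97 ± 0.78). The major urinary protein genes Mup15, Mup19, Mup17, Mup12, Mup7 and Mup9, carriers of male pheromones, were lower by log2 changes of -12.83, -11.8, -9.15, -7.98, -7.78 and -7.74. The steroid enzyme Hsd3b5 (-10 ± 1.49), the glutamate transporter Slc1a2 (508-fold lower, -8.99 ± 0.67) and the complement regulator Susd4 (-7.52 ± 1.05) were lower, and the cation transporter Slc22a3 fell from 5.17 ± 0.332 to 0.0129 ± 0.0182 CPM. Copies of the Mup, Cyp2a and Cyp2b families share reads, so single members are uncertain.

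Against control, 3636 genes were called at the end of thioacetamide, 1735 higher and 1901 lower, and 2704 without both libraries low in Malat1, of which 1872 were shared. Of the 45 called genes named for this comparison, 9 lost their call in that fit (Mmp7, Cyp2b9, Hsd3b5, Mup12, Mup7, Ehf, Cx3cr1, Sqle and Cyp8b1), Cyp2b9 without either control library, and Mup7 without control replicate 1 or TAA replicate 1. The count was 1918 without TAA replicate 1 and 8141 without control replicate 2, and a fit of these 2 groups alone called 16.

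The next comparisons asked what recovery without choline changed against the end of thioacetamide. After 1 week, 9 of 14 p53 targets had fallen (10 adjusted over the list alone), with Eda2r at -1.88 ± 0.25 and the cyclin Ccng1 at -1.49 ± 0.18. Over the p53 target genes the median was -1.27 (adjusted p = 1.01e-10, and adjusted p = 0.0323 with an estimated correlation). NRF2 targets fell in 6 of 19 (14 adjusted over the list alone), including Srxn1 (-2.06 ± 0.22) and Pgd (-1.32 ± 0.18), and cell cycle genes fell in 5 of 30 (18 adjusted over the list alone), including Ccnd1 (-1.52 ± 0.27) and the mitotic kinesin Kif20a (-2.32 ± 0.42). Over the NRF2 target genes the median was -0.95 (adjusted p = 1.34e-11, and adjusted p = 0.263 with an estimated correlation), -0.6 without TAA replicate 1 and -0.57 without recovery replicate 1. Over the cell cycle genes the median was -1.3 (adjusted p = 2.58e-12, and adjusted p = 0.35 with an estimated correlation), and -0.8 and -2 without recovery replicate 1 and 2. Bile acid genes were higher in 6 of 25 and lower in 1 (13 and 2 adjusted over the list alone), with Slc10a1 2.98-fold higher (1.58 ± 0.2) and the bile salt pump Abcb11 1.86-fold higher (0.9 ± 0.16). Over the bile acid genes the median was 0.62 (adjusted p = 6.04e-06, and adjusted p = 0.263 with an estimated correlation). Of the matrix list, 0 of 27 genes were called by edgeR either way (0 adjusted over the list alone; adjusted p = 0.0443, 0.804 with an estimated correlation, 0.648 without both libraries low in Malat1). The list call also ended without TAA replicate 1 (adjusted p = 0.776) and without recovery replicate 1 (0.701), and by narrow margins without 4 other libraries (0.05 to 0.0528). Col1a1 stood at -0.86 ± 0.45 (edgeR adjusted p = 0.322). The largest rises were in Hsd3b5 (6.55 ± 1.38), the organic anion transporters Slc22a28 (4.52 ± 0.52) and Slco1a1 (4.37 ± 0.98), Cyp4a12b (3.22 ± 0.47) and Cyp2j9 (2.56 ± 0.3). The largest falls were in Cyp1a1, a target of the dioxin receptor (-5.17 ± 0.49), Afp (-4.05 ± 0.43), Cyp3a41a (-3.93 ± 0.44), Slc22a27 (-3.43 ± 0.76) and the protease inhibitor Slpi (-3.31 ± 0.69).

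At 1 week 648 genes were called against TAA, 340 higher and 308 lower, and 1991 without both libraries low in Malat1, with 584 shared. The count moved widely with single libraries left out, both libraries of these 2 groups and libraries outside the comparison. On all libraries DESeq2 called 1468. A fit of these 2 groups alone called 5, and 1645 were called without the filter on low counts. All 18 called genes named for this comparison lost their call without replicate 1 of recovery at 1 week, and 7 did so without TAA replicate 1 (Hsd3b5, Slco1a1, Cyp4a12b, Slc22a27, Slpi, Ccnd1 and Kif20a). Hsd3b5, Slpi and Abcb11 lost theirs without TAA replicate 2, Slpi and Abcb11 without recovery replicate 2, and Slco1a1 without any 1 library of the other recovery groups.

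After 2 weeks, 20 of 30 cell cycle genes had fallen against TAA (27 adjusted over the list alone), with Ccnb1 19.1-fold lower (-4.26 ± 0.57) and Ccnd1 4.61-fold lower (-2.2 ± 0.28). The cell cycle median was -2.26 (adjusted p = 1.81e-14, and adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 20 (17 adjusted over the list alone), among them the mevalonate pathway kinase Pmvk (chromosome 3, 89454541 to 89469009; -1.44 ± 0.16) and the sterol demethylase Msmo1 (-1.96 ± 0.24). Over the cholesterol synthesis genes the median was -1.46 (adjusted p = 5.99e-11, and adjusted p = 0.241 with an estimated correlation). Matrix genes fell in 6 of 27 (6 adjusted over the list alone), with Col5a2 at -1.59 ± 0.23 and Col1a1 4.26-fold lower (-2.09 ± 0.47, edgeR adjusted p = 0.0161). Over the matrix genes the median was -0.8 (adjusted p = 8.64e-06, and adjusted p = 0.375 with an estimated correlation). The p53 targets fell in 10 of 14 (11 adjusted over the list alone), and male-biased genes rose in 8 of 11 (10 adjusted over the list alone). The p53 target median was -1.41 (adjusted p = 3.58e-10, and adjusted p = 0.0383 with an estimated correlation). Over the male-biased genes the median was 2.54 (adjusted p = 4.48e-08, and adjusted p = 0.241 with an estimated correlation). The largest rises were in Slc1a2 (6.85 ± 0.63), Hsd3b5 (6.76 ± 1.38), Mup15 (6.13 ± 1.06), Slc22a28 (5.83 ± 0.52) and Slco1a1 (5.34 ± 1.02), and the largest falls in Cyp1a1 (-5.95 ± 0.52), Slc7a11 (-5.11 ± 0.9), Cyp3a41a (-4.69 ± 0.47) and Afp (-4.64 ± 0.45).

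At 2 weeks 1904 genes were called against TAA, 887 higher and 1017 lower, and 3594 without both libraries low in Malat1, with 1644 shared. The count was 720 without TAA replicate 1, 436 and 439 without replicate 1 and 2 of recovery at 2 weeks, and 4498 and 4485 without control replicate 1 and 2, and 2861 without the filter. Col1a1 lost its call without TAA replicate 1 or either library of recovery at 2 weeks, Hsd3b5 without TAA replicate 1 or recovery replicate 2, and Slc7a11 without recovery replicate 1.

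After 4 weeks, cholesterol synthesis genes stood lower than at the end of thioacetamide in 18 of 20 members (18 adjusted over the list alone), including Pmvk (5.08-fold, -2.34 ± 0.17) and Dhcr7, the last enzyme of cholesterol synthesis (chromosome 7, 143823167 to 143848409; 5.66-fold, -2.5 ± 0.2). The cholesterol synthesis median was -2.5 (adjusted p = 9.79e-18, and adjusted p = 0.163 with an estimated correlation). Cell cycle genes were lower in 24 of 30 (27 adjusted over the list alone), with Ccnd1 11.6-fold lower (-3.53 ± 0.29), and NRF2 targets in 17 of 19 (17 adjusted over the list alone). Over the cell cycle genes the median was -2.78 (adjusted p = 1.09e-18, and adjusted p = 0.178 with an estimated correlation). The NRF2 target median was -1.32 (adjusted p = 1.6e-14, and adjusted p = 0.175 with an estimated correlation). Matrix genes were lower in 6 of 27 (9 adjusted over the list alone), with Col5a2 at -1.52 ± 0.23 and Acta2 at -1.8 ± 0.54 (edgeR adjusted p = 0.0445). The matrix median was -0.53 (adjusted p = 0.000608, and adjusted p = 0.536 with an estimated correlation), and -0.95 without recovery replicate 2. Endothelial markers were higher in 10 of 15 (11 adjusted over the list alone, with 1 lower), including the sinusoidal genes Fcgr2b (0.93 ± 0.13) and Oit3 (0.7 ± 0.13). The endothelial median was 0.64 (adjusted p = 5.01e-05, and adjusted p = 0.188 with an estimated correlation). Pck1, the first committed enzyme of glucose synthesis, was 4.56-fold higher (2.19 ± 0.18). Slc1a2 (8.28 ± 0.65), Mup15 (8.24 ± 1.05), Hsd3b5 (44.8-fold), Slco1a1 (5.28 ± 1.02) and Mup9 (4.99 ± 0.84) rose most, and Afp (-6.15 ± 0.5), Slc22a27 (-6.02 ± 0.93), Slc7a11 (-5.73 ± 0.94), Cyp2a4 (-5.49 ± 0.79) and the acetylcholine receptor gene Chrna4 (-5.05 ± 1.04) fell most.

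At 4 weeks 2569 genes were called against TAA, 1118 higher and 1451 lower, and 4551 without both libraries low in Malat1, with 2296 shared. The count was 1131 without TAA replicate 1, 899 and 893 without replicate 1 and 2 of recovery at 4 weeks, and 5559 and 5549 without control replicate 1 and 2, and a fit of these 2 groups alone called 1574. Acta2 lost its call without any 1 of the TAA and recovery libraries, Hsd3b5 without either TAA library or recovery replicate 1, and Chrna4 without either library of recovery at 4 weeks.

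The recovering livers were then set against untreated control, to show where they differed from it. Control is a single group without a recovery time in the labels, so a match in age or time to each recovery group is not known. A difference from control can be an incomplete return or a change that thioacetamide had not made. After 1 week without choline, matrix genes were higher in 11 of 27 members (20 adjusted over the list alone, with 1 lower), with Col1a1 10.2-fold higher (3.36 ± 0.5) and Col5a2 4.18-fold higher (2.06 ± 0.24). Over the matrix genes the median was 1.42 (adjusted p = 2.42e-07, and adjusted p = 0.397 with an estimated correlation). Pericentral genes were lower in 7 of 15 and higher in 3 (9 and 3 adjusted over the list alone), with Glul 9.12-fold lower (-3.19 ± 0.19). Over the pericentral genes the median was -0.87 (adjusted p = 0.000261, and adjusted p = 0.397 with an estimated correlation), and -0.56 without control replicate 1. The p53 targets were higher in 5 of 14 (7 adjusted over the list alone), including the kinase Plk2 (1.56 ± 0.17) and Eda2r (2.5 ± 0.27). Over the p53 target genes the median was 0.66 (adjusted p = 0.00234, and adjusted p = 0.397 with an estimated correlation), and 0.37 without recovery replicate 2. Of the cell cycle list, edgeR called 0 of 30 genes (0 adjusted over the list alone; median 0.71, adjusted p = 0.0697, and adjusted p = 0.74 with an estimated correlation). Cyp2a4 (8.71 ± 0.95), Cyp2b9 (7.13 ± 1.69), Gpnmb (5.96 ± 0.74), the microfibril gene Fbn2 (4.89 ± 0.78) and the secreted factor Scube3 (4.8 ± 0.97) were the most raised, and Mup19 (-8.57 ± 0.61), Mup15 (-8.13 ± 0.88), Mup17 (-7.37 ± 0.58), Susd4 (-6.73 ± 1) and Slc1a2 (-6.51 ± 0.57) the most lowered.

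At 1 week 736 genes were called against control, 329 higher and 407 lower, and 283 without both libraries low in Malat1, with 174 shared. The count was 86 and 8660 without control replicate 1 and 2, and 57 and 13 without replicate 1 and 2 of recovery at 1 week, and lay between 92 and 487 without any 1 TAA library or other recovery library except those with choline at 4 weeks (DESeq2 called 2771). In a fit of these 2 groups alone edgeR called 0 (1259 at an unadjusted p under 0.05), and without the filter it called 3618. With the replicate number as a block it called 1483. Cyp2b9 lost its call without any single control, TAA or recovery library, Scube3 without most of them, Col1a1 and Fbn2 without control replicate 1 or recovery replicate 2, Cyp2a4 without control replicate 1, and Susd4 without either library of recovery at 1 week.

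After 2 weeks without choline, 2 of 20 cholesterol synthesis genes were lower than in control (13 adjusted over the list alone), Pmvk (2.82-fold, -1.49 ± 0.16) and Fdps, which makes farnesyl diphosphate (2.87-fold, -1.52 ± 0.28). Over the cholesterol synthesis genes the median was -0.89 (adjusted p = 6.64e-07, and adjusted p = 0.66 with an estimated correlation). Pericentral genes were lower in 2 of 15 (9 adjusted over the list alone, with 2 higher), with Glul 4.35-fold lower (-2.12 ± 0.18). The pericentral median was -0.69 (adjusted p = 0.00149, and adjusted p = 0.66 with an estimated correlation), and -0.36 without control replicate 1. Of the matrix list, edgeR called 0 of 27 genes (6 higher adjusted over the list alone), and Col1a1 stood at 2.13 ± 0.48 (edgeR adjusted p = 0.0779). The matrix median was 0.71 (adjusted p = 0.00091, adjusted p = 0.66 with an estimated correlation and 0.203 without control replicate 2). Among called genes of at least 5 CPM in the higher group that passed the naming rule, the most raised were Cyp2a4 (6.75 ± 0.89), the muscarinic receptor gene Chrm3 (2.82 ± 0.23), Cyp2j9 (1.97 ± 0.29), Eda2r (1.93 ± 0.27) and the transcription factor Klf11 (1.87 ± 0.29). The most lowered were Mup19 (-8.07 ± 0.59), Mup15 (-6.7 ± 0.82), Mup17 (-5.97 ± 0.54), Susd4 (-5.51 ± 0.93) and Nxpe2 (-5.04 ± 0.62).

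At 2 weeks 69 genes were called against control, 26 higher and 43 lower, and 165 without both libraries low in Malat1, with 50 shared; 4377 genes had an unadjusted p under 0.05 and DESeq2 called 1517. The count was 44 and 7958 without control replicate 1 and 2, 3 and 8 without replicate 1 and 2 of recovery at 2 weeks, and between 31 and 45 without other recovery libraries except replicate 1 with choline at 4 weeks. In a fit of these 2 groups alone edgeR called 0 (818 at an unadjusted p under 0.05), and without the filter it called 2677. Without recovery replicate 1, Chrm3, Mup19 and Glul of the 13 called genes named here were still called, and 6 were without recovery replicate 2. Fdps and Susd4 lost their call without almost any recovery library, with Cyp2a4 and Klf11 also lost without control replicate 1.

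After 4 weeks without choline, 17 of 20 cholesterol synthesis genes were lower than in control (18 adjusted over the list alone), including Pmvk (54.4 ± 5.25 CPM in control and 10.3 ± 0.734 CPM at 4 weeks, SD, n = 2; log2 -2.4 ± 0.17) and Dhcr7 (82.7 ± 2.22 and 17.3 ± 0.467 CPM; -2.26 ± 0.19). The cholesterol synthesis median was -1.53 (adjusted p = 2.33e-13, and adjusted p = 0.442 with an estimated correlation). Genes of fatty acid and triglyceride synthesis were lower in 10 of 20 and higher in 1 (14 and 1 adjusted over the list alone), with Thrsp, a regulator of lipogenesis (chromosome 7, 97412938 to 97417730), at 316 ± 15.9 CPM in control and 14 ± 3.34 CPM at 4 weeks (-4.5 ± 0.43), and the acetyl-CoA synthetase Acss2 4.3-fold lower (-2.11 ± 0.23). The fatty acid synthesis median was -0.76 (adjusted p = 4.48e-05, and adjusted p = 0.442 with an estimated correlation). Matrix genes were higher in 9 of 27 (17 adjusted over the list alone, with 2 lower), with Col1a1 4.66-fold higher (2.22 ± 0.48) and Col5a2 2.18-fold higher (1.13 ± 0.24). Over the matrix genes the median was 1.05 (adjusted p = 0.0011, adjusted p = 0.715 with an estimated correlation and 0.132 without control replicate 2), and 0.57 without recovery replicate 2. Cell cycle genes were lower in 6 of 30 (8 adjusted over the list alone), including the replication helicase Mcm5 (-1.86 ± 0.33), and Glul was 3.44-fold lower (-1.78 ± 0.18). The cell cycle median was -0.74 (adjusted p = 0.00134, adjusted p = 0.715 with an estimated correlation, and a median of -0.27 with an adjusted p of 0.271 without control replicate 2). Mmp7 stood at 0.0628 ± 0.0405 CPM in control and was called higher, with Cyp2a4 (5.41 ± 0.86), the metallothionein Mt2 (4.8 ± 0.73), Pdgfrl (4.04 ± 0.51) and the clock repressor Nr1d1 (3.48 ± 0.63), and Mup19 (-8.15 ± 0.6), Susd4 (-5.39 ± 0.92), Mup17 (-5.3 ± 0.52), Capn8 (-4.85 ± 1.23) and Cyp2c69 (-4.67 ± 0.88) were the most lowered.

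At 4 weeks 3368 genes were called against control, 1267 higher and 2101 lower, and 2107 without both libraries low in Malat1, with 1558 shared. The count was 940 and 9044 without control replicate 1 and 2, 123 and 94 without replicate 1 and 2 of recovery at 4 weeks, and 2216 without replicate 2 of recovery with choline at 2 weeks. In a fit of these 2 groups alone edgeR called 0, with 2033 at an unadjusted p under 0.05, and DESeq2 on all libraries called 4631. Mmp7, Nr1d1, Capn8, Col5a2 and Col1a1 lost their call without control replicate 1 or either library of recovery at 4 weeks, Cyp2a4 without control replicate 1, and Susd4, Cyp2c69 and Mcm5 without either of the latter.

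**Figure D2:**
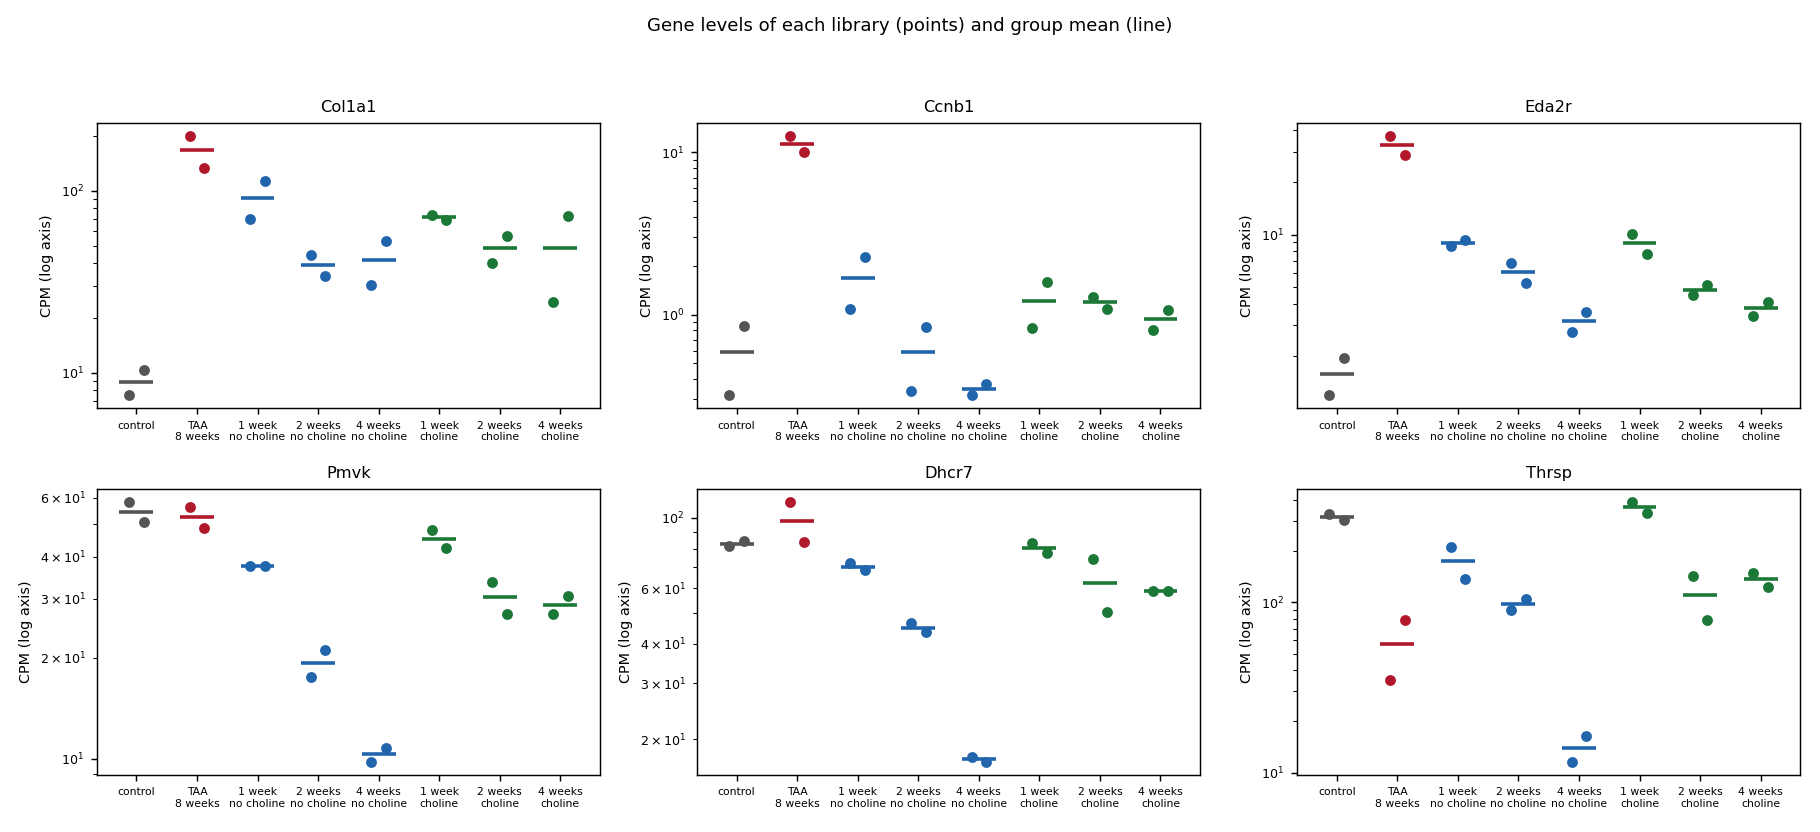
CPM on log axes of Col1a1, Ccnb1, Eda2r, Pmvk, Dhcr7 and Thrsp, 1 point per library, for the 8 groups of 2. Pmvk averages 54.4 CPM in control, 10.3 CPM after 4 weeks without choline and 28.8 CPM after 4 weeks with choline.

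Of the 3636 genes called with thioacetamide, 603 (16.6%) were called in the same direction against control after 1 week, 51 (1.4%) after 2 weeks and 1246 (34.3%) after 4 weeks. Of the same 3636 genes, 2, 3 and 62 were called in the opposite direction after 1, 2 and 4 weeks. Independent lists of these sizes would share 2.1%, 0.2% and 9.8% in the same direction. Groups simulated without any effect shared 0% in 10 sets at each time. Their means were set to those of the same control libraries, so the simulation could not measure a share that comes from shared controls. The control libraries are too few to split, so part of the excess may come from the shared controls. Each left-out library moved these shares widely, from 0.4% to 79%, 0.1% to 70.2% and 1.6% to 74.6%. Without both libraries low in Malat1 they were 7.3%, 3.1% and 20.2%, without the filter 50.5% and 31.7% at 1 and 2 weeks, and by DESeq2 41.7% and 18.8%. With the replicate number as a block the share at 1 week was 28.2%. The median share of the log2 change that remained was 58.7%, 37.5% and 48.1% after 1, 2 and 4 weeks for the genes called higher, and 58%, 43% and 53.9% for those called lower. Both changes were taken against the same control libraries, so part of what remained may come from those controls too. Livers at 4 weeks were also set directly against livers at 2 weeks, and 46 genes were called, 23 higher and 23 lower, with 1524 at an unadjusted p under 0.05 (chance gives 865). The 865 assumes evenly spread p-values, and the same fit gave only 154 for choline at 1 week, so it is an uncertain reference.

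The remaining comparisons asked what choline in the drinking water changed during recovery. After 1 week, 0 genes were called by edgeR, with 154 at an unadjusted p under 0.05, fewer than the 865 of 17292 that chance gives, and 2 called by DESeq2. Without the filter on low counts edgeR called 44. A fit of these 2 groups alone called 0, with 568 of 16277 genes at an unadjusted edgeR p under 0.05. The number of genes with a small p thus depends on which libraries share the fit. The 865 assumes evenly spread p-values and is an uncertain reference for this fit, here and below. For the same reason, 0 calls do not show the absence of a choline effect. The genes with the smallest p, none passing, were the predicted gene Gm45808 (91 counts with and 0 without choline), the secreted peptide gene Enho (-1.71 ± 0.34), the choline phosphodiesterase Enpp6 (1.22 ± 0.27), the ceramidase Acer2 (0.71 ± 0.18) and G6pdx of the pentose phosphate pathway (1.26 ± 0.33). Of the fatty acid and triglyceride synthesis list 16 of 20 members had values above 0, with 0 called by edgeR (0 adjusted over the list alone), Acss2 at 0.63 ± 0.22 and Thrsp at 1.05 ± 0.37. Over the fatty acid synthesis genes the median was 0.47 (adjusted p = 1.59e-07, and adjusted p = 0.209 with an estimated correlation), and 0.16 and 0.71 without replicate 1 and 2 with choline. Of the cell cycle list 28 of 30 members had values below 0, with 0 called by edgeR (0 adjusted over the list alone) and a median of -0.28 (adjusted p = 0.00273, and adjusted p = 0.799 with an estimated correlation). Its call ended without replicate 1 with choline (adjusted p = 0.958), and its median was 0.25 without replicate 2 lacking choline. The preset test also called cholesterol synthesis (median 0.17), stellate cell (0.12), Kupffer cell (0.27), endothelial (0.18), pericentral (-0.32), periportal (0.12), immediate early (0.64) and mitochondrially encoded genes (0.14). None of these calls held with an estimated correlation, and each ended without some single library of that week.

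After 2 weeks with choline, 0 genes were called by edgeR, with 201 at an unadjusted p under 0.05 (chance gives 865) and 0 called by DESeq2. The edgeR fit of these 2 groups alone gave 1073 of 15569 genes such a p, so the 201 depends on which libraries share the fit. A fit of these 2 groups alone called 7, 55 were called without the filter, and 2 were called without replicate 2 of recovery without choline at 2 weeks. The smallest p-values, none passing, belonged to Hmga1b (3.1 ± 0.65), a chromatin gene with near-identical copies, the predicted gene Gm6644 (0 counts with and 23 without choline), Acss2 (1.02 ± 0.22), Pmvk (0.65 ± 0.16) and CT010467.2 (1.31 ± 0.33). All 20 cholesterol synthesis genes had values above 0, with 0 called over all genes tested (2 adjusted over the list alone). Over the cholesterol synthesis genes the median was 0.51 (adjusted p = 1.1e-17, and adjusted p = 0.473 with an estimated correlation). The preset test also called cholangiocyte (median 0.47), hepatocyte identity (-0.12), NRF2 target (0.2), acute phase (-0.15) and mitochondrially encoded genes (-0.2). Each of these calls was lost with an estimated correlation and without some single library of that week.

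After 4 weeks with choline, 9 genes were called, all 9 higher. Among them were Thrsp (14 ± 3.34 CPM without and 136 ± 18 CPM with choline, SD, n = 2; 9.75-fold, log2 3.29 ± 0.41, edgeR adjusted p = 0.0218), the sterol pathway genes Fdps (3.99-fold, 2 ± 0.28), Dhcr7 (17.3 ± 0.467 and 58.8 ± 0.011 CPM; 3.4-fold, 1.76 ± 0.19, edgeR adjusted p = 0.0118), Msmo1 (3.11-fold, 1.64 ± 0.24) and Pmvk (10.3 ± 0.734 and 28.8 ± 2.58 CPM; 2.79-fold, 1.48 ± 0.17, edgeR adjusted p = 0.0118), the acetyltransferase gene Nat8f5 (3.42-fold, 1.78 ± 0.23), the vitamin C transporter Slc23a1 (3.03-fold, 1.6 ± 0.21) and Mmab of vitamin B12 metabolism (2.19-fold, 1.13 ± 0.16). All 20 cholesterol synthesis genes had values above 0, and the list rose with 4 called (17 adjusted over the list alone). The cholesterol synthesis median was 1.19 (adjusted p = 3.51e-33, and adjusted p = 0.0445 with an estimated correlation). All 20 fatty acid and triglyceride synthesis genes did so too, with 1 called (12 adjusted over the list alone), Fasn at 1.8 ± 0.33 (edgeR adjusted p = 0.124) and Acss2 at 1.4 ± 0.22 (edgeR adjusted p = 0.0566). The fatty acid synthesis median was 0.87 (adjusted p = 7.72e-19, and adjusted p = 0.0241 with an estimated correlation). Of the cell cycle list, 28 of 30 members had values above 0 and edgeR called 0 (1 adjusted over the list alone), and the acute phase list had 0 called (3 lower adjusted over the list alone). Over the cell cycle genes the median was 0.75 (adjusted p = 1.51e-10, and adjusted p = 0.624 with an estimated correlation). The acute phase median was -0.54 (adjusted p = 0.00063, adjusted p = 0.923 with an estimated correlation). Its call ended without replicate 1 lacking choline (median 0.1, adjusted p = 0.674) and without replicate 2 with it (-0.22, adjusted p = 0.247). Calls of cholesterol sensing (median 0.1), bile acid (0.16), NRF2 target (0.16) and adipocyte genes (-0.6) were lost with an estimated correlation and without some single library of that week. The matrix list did not pass (median 0.03, adjusted p = 0.579, and adjusted p = 0.928 with an estimated correlation), and Col1a1 stood at 0.22 ± 0.45, with a 95% confidence interval from -0.77 to 1.2.

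Without any 1 of the 4 libraries at 4 weeks, 0 genes were called for choline at 4 weeks, where 1017 had an unadjusted p under 0.05 and DESeq2 called 98 with all libraries; Dhcr7 and Pmvk alone of the 8 genes named here were still called without either library with choline at 1 week. The count was 2 without either library with choline at 1 week, 5 without either library without choline at 1 week or with choline at 2 weeks, 46 and 45 without control replicate 1 and 2, and 144, including all 8, without both libraries low in Malat1. A fit of these 2 groups alone called 14, with 1803 of 15913 genes at an unadjusted edgeR p under 0.05, and 228 were called without the filter.

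As the mean over the 3 times, 3 genes were called with choline, all higher: Pmvk (1.74-fold, log2 0.8 ± 0.09, edgeR adjusted p = 0.0369), Acss2 (2.02-fold, 1.02 ± 0.13, edgeR adjusted p = 0.0401) and Dhcr7 (1.75-fold, 0.81 ± 0.11, edgeR adjusted p = 0.0445). The cholesterol synthesis list rose (2 of 20 called, 17 adjusted over the list alone), and so did the fatty acid and triglyceride synthesis list (1 of 20 called, 13 adjusted over the list alone). Over the cholesterol synthesis genes the median was 0.61 (adjusted p = 3.89e-40, and adjusted p = 0.0251 with an estimated correlation). Over the fatty acid synthesis genes the median was 0.45 (adjusted p = 8.86e-20, and adjusted p = 0.0205 with an estimated correlation). The matrix list did not pass (median 0.01, adjusted p = 0.515, and adjusted p = 0.944 with an estimated correlation), nor did the choline and one-carbon list (median 0.01, adjusted p = 0.621, and adjusted p = 0.944 with an estimated correlation). Preset calls of endothelial (median 0.11), cell cycle (0.13), NRF2 target (0.11) and acute phase genes (-0.16) were lost with an estimated correlation and without some single recovery library. Col1a1 stood at 0.05 ± 0.26 with a 95% confidence interval from -0.52 to 0.62, and Acta2 at 0.41 ± 0.31. Of the choline genes, Chdh, which oxidises choline to make betaine, Bhmt, which uses betaine as methyl donor, and Pemt, which makes phosphatidylcholine, stood at 0.11 (-0.16 to 0.39), 0.31 (-0.28 to 0.9) and 0.11 (-0.22 to 0.44). The calls of Pmvk, Acss2 and Dhcr7 were lost without any 1 of 11 of the 12 recovery libraries, the exception being replicate 2 with choline at 2 weeks. The fit called 15 genes without both libraries low in Malat1, including all 3. The count was 5 to 7 without any 1 control or TAA library. An additive model of time and choline, fitted to the 12 recovery libraries alone, called 0 genes by edgeR. In it 1286 of 16894 genes had an unadjusted edgeR p under 0.05. Group means fitted to the same 12 libraries called 15, with 1561 of 16894 genes at such a p. With group means over all 16 libraries, where 3 genes were called, 528 had such a p (chance gives 865). On all libraries DESeq2 called 42 and edgeR without the filter 123.

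The test of whether the choline effect differed between the times called 0 genes by edgeR, with 330 at an unadjusted p under 0.05 (chance gives 865) and 19 called by DESeq2. Without the filter it called 151, and without both libraries low in Malat1 it called 0, with 1400 genes (7.8%) at an unadjusted p under 0.05. Across the 17292 genes, which are not independent replicates, the choline effects of different times had Pearson correlations of 0.005 (1 and 2 weeks), -0.007 (1 and 4 weeks) and -0.029 (2 and 4 weeks).

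**Figure D3:**
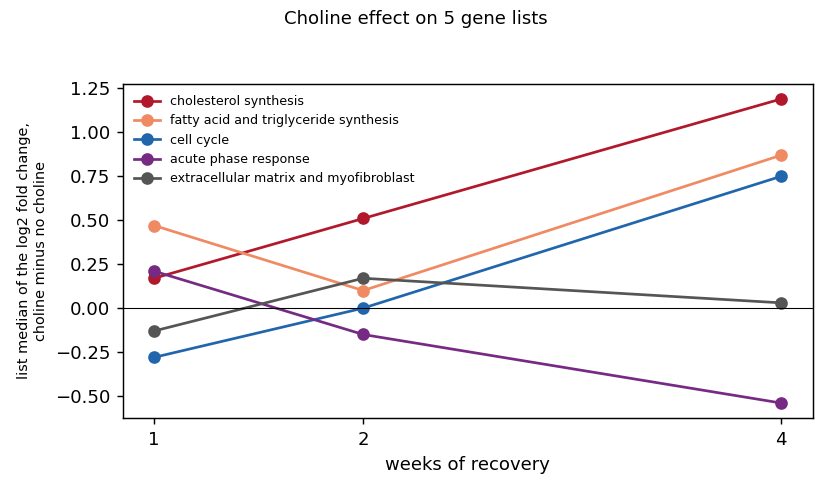
Median log2 fold change of 5 gene lists, choline minus no choline, at 1, 2 and 4 weeks of recovery (2 libraries per arm and time). The cholesterol synthesis median goes from 0.17 to 0.51 to 1.19, and the matrix median is 0.03 at 4 weeks.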

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

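The tests of depth, ribosomal RNA, scaling, fasting, time of day and control replicate 1, the splits of the fatty acid list and the tests of week differences were chosen only after the results they bear on were seen. A test of the gap between an outlying sample and its group was not run, because it needs 4 samples in a group.

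Control replicate 1 and TAA replicate 1 were low in Malat1, at 146 and 1020 CPM. Lower depth is argued against by their totals, 32.5 and 33.6 Mcounts (mega-counts) against 23.1 to 32.1 Mcounts in the others, and carry-over of ribosomal RNA by TAA replicate 1, which held 0.21% of such counts against 0.446% in a library with 6800 CPM of Malat1, and by recovery with choline at 1 week replicate 2, which held 1.409% of such counts and 6020 CPM of Malat1. A general loss of nuclear RNA was set a bound in advance, a median log2 ratio of replicate 1 to replicate 2 below -0.5 over 345 antisense genes in both groups: the median was -0.37 in control (bootstrap SE 0.09, added after the value was seen) and -0.52 in TAA (SE 0.06), so the bound was missed in control. The other groups lay between -0.07 and 0.11, and what lowered these RNAs in both libraries stays open. No biological explanation was tested, since the labels give these libraries no treatment of their own.

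Genes of cholesterol and fatty acid synthesis were higher with choline at 4 weeks. Relative to the mean of all libraries, the cholesterol list median log2 level was -0.26 and 0.02 with choline and -1.26 and -1.4 without. For the fatty acid list it was 0.19 and 0.03 with choline and -0.72 and -0.63 without. The 2 control libraries stood at 0.47 and 0.12 for cholesterol and 0.2 and 0.21 for fatty acid synthesis. Livers with choline were not tested against control. Scaling of the libraries is argued against for the cholesterol list, whose median lay 1.21 above the -0.02 of all genes (adjusted p = 0.0445 with an estimated correlation), a distance that one factor per library cannot change. Fasting of the livers without choline cannot be told apart from choline: of 18 fasting-induced genes 13 were lower with choline, the way fasting would move them, but the median was -0.1 (camera p = 0.069, and 0.395 with an estimated correlation) and the labels give no feeding state. Sampling at another time of day cannot be told apart from choline, since the clock list had an adjusted p of 0.366 (adjusted p = 0.923 with an estimated correlation), which does not show an equal phase, and the labels give no time. The choline in the water, the treatment the labels name, stays among the open explanations.

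More genes were called against control at 4 weeks (3368) than at 2 weeks (69). Control replicate 1 alone is argued against by the 4-week count of 940 without it, against 44 at 2 weeks, but the counts were 9044 and 7958 without control replicate 2, 0 and 0 by edgeR in fits of the compared groups alone (2033 and 818 at an unadjusted p under 0.05; DESeq2 on all libraries called 4631 and 1517), and 123 or 94 at 4 weeks without either of its libraries. The direct contrast of the livers at 4 and 2 weeks called 46 genes, under the bound of 50 set in advance. Many 2-week values lying just short of the threshold would give such a result. Against control, 4377 genes at 2 weeks and 6590 at 4 weeks had an unadjusted edgeR p under 0.05 in the fit of all libraries. In the direct contrast 1524 genes had such a p, where evenly spread p-values would give 865, an uncertain reference for this fit. Time of day cannot be told apart from recovery time: the clock list had an adjusted p of 0.0491 between the 2 times (adjusted p = 0.46 with an estimated correlation), Per1 differed by a log2 change of 3.15 and Nr1d1 by 0.38, and the labels give no time. Nr1d1 stood at 7.19 ± 2.57 CPM in control, and without choline at 3.7 ± 0.279, 61.5 ± 47.1 and 80.1 ± 6.89 CPM after 1, 2 and 4 weeks. The clock gene Arntl stayed at 27.6 ± 7.37 CPM in control and 29.9 ± 1.97 CPM at 4 weeks. Time of day thus cannot be told apart from recovery in the comparisons with control either. A difference from recovery time itself also stays open.

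Choline effects that differed between weeks are given as list medians of log2 differences, each with an adjusted p under 0.05 in camera at the preset correlation on the difference itself, and none below 0.05 with an estimated correlation. From 1 to 2 weeks the choline effect differed by 0.36 for cholesterol synthesis, -0.16 for stellate cell markers, 0.58 for cholangiocyte markers, -0.46 for Kupffer cell markers, -0.29 for endothelial markers and -0.14 for hepatocyte identity genes. It differed over the same weeks by 0.2 for pericentral, -0.21 for periportal, 0.33 for cell cycle, -0.33 for acute phase, -0.25 for clock, -0.37 for immediate early and -0.34 for mitochondrially encoded genes. From 1 to 4 weeks it differed by 1.03 for cholesterol synthesis, 0.12 for cholesterol sensing, 0.21 for bile acid, 0.44 for fatty acid synthesis, -0.32 for stellate cell, 0.33 for pericentral, -0.12 for periportal and 1 for cell cycle genes. It also differed by -0.15 for p53 targets, -0.75 for acute phase, -0.17 for clock, -0.36 for immediate early and -0.66 for adipocyte genes. From 2 to 4 weeks it differed by 0.59 for cholesterol synthesis, 0.15 for cholesterol sensing, 0.28 for bile acid, 0.6 for fatty acid synthesis and 0.15 for one-carbon genes. It differed there also by -0.62 for cholangiocyte markers, 0.23 for hepatocyte identity, 0.57 for cell cycle and 0.29 for mitochondrially encoded genes.

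The mean choline effect was compared with splits of the 12 recovery libraries into arms within each week, 100 drawn, the real one included. As many genes as the real 3 were called in 1 split, the real one, and the highest of the others called 1. Such a count was rare among the 100 splits, which does not exclude chance. As many lists as the real 6 were called in 96 splits, and the highest of the others called 20, so chance cannot be excluded for the count of lists. An absolute median of the cholesterol synthesis list as large as the real 0.613 came from 3 splits (highest of the others 0.632). Both other splits kept 1 of the 6 choline libraries in 1 arm. For the fatty acid list, a median as large as 0.45 came from 2 splits (highest of the others 0.51). Medians of this size were rare among the splits, which does not exclude chance. The fatty acid list was also chosen for this test after its rise was seen.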

How the results depend on the processing

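Leaving out both libraries low in Malat1 and the tests of week differences were chosen only after the data were seen. Fits without both low libraries rest on a single control library and a single TAA library. Scaling by DESeq2 size factors ended no call among the 153 called of 181 named results and kept each count within 1.5 times. No filter and DESeq2's test ended 0 of the 153 calls and added 16 and 8, and leaving out some single library ended 62 and leaving out both low libraries 26. Rounding low counts and 2 libraries per group limit the precision of rare transcripts. Simulated genes with a mean of at least 5 CPM, changed 2-fold, were called in 38% for TAA against control and 44% for choline at 4 weeks. The cause of the changes was not tested, except that fits of the compared groups alone rest on fewer libraries.

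Fits of the compared groups alone called 16 genes for TAA against control, 5 and 1574 against TAA at 1 and 4 weeks, 0, 0 and 0 against control at 1, 2 and 4 weeks, 7 and 14 for choline at 2 and 4 weeks and 15 for its mean. Without the filter, 1645 and 2861 were called against TAA at 1 and 2 weeks, 3618 and 2677 against control at 1 and 2 weeks, 44, 55 and 228 for choline at 1, 2 and 4 weeks, 123 for its mean and 151 for its interaction with time. Of the genes called with thioacetamide, 50.5% and 31.7% were then called against control at 1 and 2 weeks, and the choline effects at 1 and 2 weeks correlated at -0.016. DESeq2 called 1468 against TAA at 1 week, 2771 and 1517 against control at 1 and 2 weeks, 2 and 98 for choline at 1 and 4 weeks, 42 for its mean and 19 for the interaction, with shares of 41.7% and 18.8% and a correlation of -0.001 at 2 and 4 weeks. The additive model of time and choline, on the 12 recovery libraries alone, called 0 genes by edgeR for the mean. Group means called 15 on the same 12 libraries and 3 on all 16.

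Without both low libraries, 1991, 3594 and 4551 genes were called against TAA and 283, 165 and 2107 against control at 1, 2 and 4 weeks, 144 for choline at 4 weeks, 15 for its mean, and 3 lists for choline at 2 weeks. The shares were 7.3%, 3.1% and 20.2%, and the correlation at 1 and 2 weeks -0.012. With an estimated correlation, 2 lists were called for TAA against control, 1, 1 and 0 against TAA, 0, 0 and 0 against control, 0, 0 and 2 for choline at 1, 2 and 4 weeks, and 2 for its mean.

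The replicate number as a block raised the count against control at 1 week to 1483 and the share to 28.2%, and moved no other count by over 1.5 times. The log2 differences of replicate 1 from replicate 2 correlated above 0.1 in 8 of 28 pairs of groups and below -0.1 in 2 (range -0.21 to 0.59). The numbers were therefore not taken as a pairing. The value of 0.59 belongs to control and TAA, where replicate 1 of each is the library low in Malat1.

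With each library left out in turn, counts ranged from 1918 to 8141 for TAA against control, 1 to 2829, 436 to 4498 and 893 to 5559 against TAA, and 13 to 8660, 3 to 7958 and 94 to 9044 against control. They ranged from 0 to 0, 0 to 2 and 0 to 46 for choline, 0 to 7 for its mean and 0 to 0 for the interaction. Lists called ranged from 20 to 26 for TAA against control, 13 to 21, 21 to 23 and 18 to 24 against TAA, 15 to 19, 6 to 14 and 7 to 15 against control, 8 to 15, 2 to 8 and 7 to 17 for choline, and 6 to 12 for its mean. The shares ranged from 0.4% to 79%, 0.1% to 70.2% and 1.6% to 74.6%, and the correlations from -0.038 to 0.024, -0.061 to 0.051 and -0.05 to 0.049. The choline value of Col1a1, never called, changed sign. At 1 week it ranged from -0.66 to 0.03, the latter without replicate 2 lacking choline. At 4 weeks it ranged up to 0.81 and was -0.13 and -0.77 without replicate 1 lacking choline or replicate 2 with it. Its mean ranged up to 0.25 and became -0.05, -0.01 and -0.07 without 1-week replicate 1, 2-week replicate 2 or 4-week replicate 1 lacking choline, and -0.04 and -0.28 without 2-week or 4-week replicate 2 with choline.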

Other observations

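The tests of glucocorticoid-induced genes and of 4 against 2 weeks with choline were chosen only after the results they bear on were seen.

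Thioacetamide also lowered 12 of 20 genes of hepatocyte identity and secretion, with 0 higher (16 and 0 adjusted over the list alone; median log2 -0.95, adjusted p = 4.42e-08, 0.247 with an estimated correlation; median -0.42 without control replicate 1), and 8 of 13 mitochondrially encoded genes, with 0 higher (13 and 0 adjusted over the list alone; median -0.96, adjusted p = 7.51e-07, 0.126 with an estimated correlation). Endothelial markers were lower in 7 of 15 and higher in 1 (8 and 1 adjusted over the list alone; median -0.35, adjusted p = 0.00112, 0.22 with an estimated correlation). Genes of the unfolded protein response were lower in 8 of 15 (10 adjusted over the list alone; median -1.33, adjusted p = 7.05e-05, 0.31 with an estimated correlation), and this call ended without control replicate 1 (median -0.66, adjusted p = 0.066). Lists that were not called included Kupffer cell markers (median -0.08, adjusted p = 0.928), lymphocyte markers (0.71, 0.568), stellate cell markers (-0.1, 0.0621) and xenobiotic P450 genes (-0.23, 0.233).

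Between 2 and 4 weeks of recovery without choline, 46 genes were called, of which 3 are given here, chosen after their values were seen. Per1, a clock gene that glucocorticoids also induce, stood at 6.95 ± 1.3 CPM at 2 weeks and 61.8 ± 14.2 CPM at 4 weeks (SD, n = 2; log2 3.15, edgeR adjusted p = 0.00203). The metallothionein Mt2, a metal-binding protein, stood at 1.17 ± 0.754 and 19.4 ± 12.4 CPM (log2 4.06, edgeR adjusted p = 0.0431), and Pck1 at 1790 ± 194 and 4290 ± 173 CPM (log2 1.26, edgeR adjusted p = 0.0213). With choline, Per1 stood at 9.06 ± 3.02 CPM at 2 weeks and 35.3 ± 2.66 CPM at 4 weeks (log2 1.96, edgeR adjusted p = 0.0583), Mt2 at 0.535 ± 0.129 and 1.46 ± 0.168 CPM (1.44, edgeR adjusted p = 1), and Pck1 at 1510 ± 37.9 and 2930 ± 242 CPM (0.96, edgeR adjusted p = 0.123). The choline effect on Mt2 (log2 -3.73, edgeR adjusted p = 0.124) did not pass. Cholesterol synthesis genes were lower at 4 than at 2 weeks (median log2 -0.86, adjusted p = 9.28e-17, and adjusted p = 0.268 with an estimated correlation), as were those of fatty acid synthesis (-0.58, adjusted p = 9.81e-09, and adjusted p = 0.252 with an estimated correlation).

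A candidate explanation for the difference between the arms at 4 weeks is a higher glucocorticoid exposure of the livers without choline, such as from handling or stress. All 14 glucocorticoid-induced genes listed for the test were lower with choline at 4 weeks, with a median log2 change of -0.56 (camera p = 8.05e-07, and 0.000777 with an estimated correlation), but Sult1e1 had 2 counts in the 4 libraries compared. Of the other 13 (median -0.49, camera p = 1.33e-06, and 0.000937 with an estimated correlation), 8 were lower by over 1 SE, with Errfi1 and Klf9 at -0.05 and -0.09, and at 1 and 2 weeks 4 of the 14 were lower (medians 0.11 and 0.12). From 2 to 4 weeks the list was higher in both arms, by a median of 1.4 without choline (13 of 14 genes, camera p = 2.03e-16, and 2.28e-05 with an estimated correlation) and 0.71 with it (10 of 14, camera p = 9.53e-09, and 0.000288 with an estimated correlation), so a rise is not confined to the livers without choline. The values of 9 of the 14 genes had been seen before the list was written, so the test is not independent, and exposure cannot be told apart from an effect of choline in this design.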
